A study of Mus musculus with 4 samples.

How the data were processed

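RNA was measured on 4 Affymetrix mouse whole-genome expression arrays, 1 per sample, in 2 pseudopodia samples and 2 cell body samples of NIH/3T3 cells, a fibroblast line from mouse embryos. Per the labels' protocols, the cells sat in serum-free medium on a porous membrane coated with fibronectin on its lower face only, and sent protrusions through the pores for 1 h. They were then fixed in 0.3% formaldehyde for 10 min. One compartment was wiped off the membrane by hand and the other was scraped into a buffer in which crosslinks were reversed at 70 °C for 45 min. Total RNA was extracted with Trizol LS and labelled with biotin by the array maker's standard protocol, per the labels' protocols.

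The deposited values are probe set intensities on a linear scale, 1 column per array. The summary of probes into probe sets, the scaling between arrays and the software are not given in the sources used here. The lowest value on each array is exactly 20, a floor shared by 30.5% to 34.8% of the 45037 non-control probe sets (45101 with controls). A level at the floor is therefore only an upper bound. Median intensities were 41.2 and 45.6 on the pseudopodia arrays and 44.3 and 40.5 on the cell body arrays. The highest intensities were 14372, 13766, 15025 and 14761 in the same order. The array medians lay close enough together that no further scaling was applied in the main setting. The number of arrays, 2 per compartment, limits the precision of every value below. The array records list 1 chip lot, 1 fluidics station, 1 hybridization time, 1 scan day and 1 scanner for all 4 arrays, with a fluidics module for each array, so no batch recorded there could be fitted. Batches of culture, RNA extraction or labelling are not given in the sources used here.

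The log2 values were computed here as log2(intensity + 1), and a fold is the antilog of a difference on that scale, which understates the change of dim genes. The 64 control probe sets were left out of the tests. Of the 45037 others, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 were unnamed here. Gene IDs of 34741 of the 1-symbol probe sets matched a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. Since the annotation behind the arrays may follow another build, no coordinates are given. Each of the 18193 genes was represented by its brightest 1-symbol probe set over the 4 arrays. Genes whose mean fell under the median of the non-control probe sets (log2 5.42, an intensity of 42.0) were then left out, which left 11320 genes to test. Probe sets with several symbols or none entered no gene-level comparison. Several members of a family can share probes, and a probe set of a gene need not follow its others; among called genes with a second probe set above the filter, 725 of 807 (89.8%) second probe sets differed in the same direction, against 69.1% of 4109 among genes not called, and both probe sets of a gene were read on the same arrays.

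Pseudopodia were compared with cell bodies by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate) with Benjamini-Hochberg adjustment over the 11320 genes. Every adjusted p given for a gene is from that fit, at a threshold of 0.05, with 2 residual and 2.90 prior degrees of freedom. A split of 4 arrays into pairs can be made in 3 ways, so a permutation test of a lone gene cannot give a p under 33.3%, and none was run. Genes at least 2-fold apart (log2 difference of 1) whose arrays did not overlap were counted as a description. Where both arrays of a compartment lay at the floor, the geometric mean of the other compartment's arrays over the floor of 20 is given as "at least N-fold".

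Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists that had at least 5 tested members. Camera was repeated with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance without setting them against other genes, was run as well. With an estimated correlation, camera uses the 2 residual degrees of freedom of the fit, which leaves it little power. A list that did not pass in that form is therefore not shown to lack a shift. Before the data were examined, 26 lists were fixed: known protrusion RNAs, cytoplasmic ribosomal proteins, translation factors, oxidative phosphorylation, the mitochondrial genome, mitochondrial ribosomal proteins, actin and Arp2/3, focal adhesion, microtubules and motors, Rab GTPases, extracellular matrix and secreted proteins, endoplasmic reticulum chaperones and translocon, nuclear-retained noncoding RNAs, immediate early and short-lived transcripts, C2H2 zinc finger genes, splicing factors, replication-dependent histones, mitosis, DNA replication, glycolysis, proteasome, cholesterol synthesis, cytosolic chaperones, epithelial markers, haematopoietic markers and fibroblast markers. The mitochondrial genome list had 0 tested members. The first list was remembered from published work on RNAs bound by APC in fibroblast protrusions, to which these arrays belong.

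The test, the filter, the alternatives and the rule for named genes were likewise set before the data were examined. The rule named the 12 genes with the largest difference in each direction among those past the threshold with no overlap of arrays, every tested known protrusion RNA, the 2 to 4 members of each described list with the smallest p and the brightest member of lists of abundant genes, and Actb and Gapdh. Hspg2, Fos, Lims1, Malat1, Kcnq1ot1 and some members of small counts were named outside the rule, after their values were seen. Genes of uncertain identity (clones, predicted genes) were skipped, which removed 0 genes among those higher and 1 among those lower. Alternatives were another filter or none, quantile normalization, median centring, a pseudocount of 16, other ways to treat the probe sets of a gene, other variance models and tests, another threshold, a block for the replicate number and each array left out in turn. A setting with only genes above the floor on all 4 arrays was chosen after seeing the data.

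The procedure was tested on simulated data: 20 sets of 11320 genes with the measured levels, 200 of them changed. Each gene's variance was drawn from the distribution that limma fitted, and the noise was independent between genes. At 2 arrays per compartment, 33.2% of genes changed by 1.5 log2 and 3.05% of those changed by 1 log2 were recovered, and 4.99% of calls were false. With as many changed genes as were called here, 69.8% were recovered and 4.45% of calls were false. These changes had the sizes fitted for the called genes, so that recovery may be too high. Of 180 simulated lists without a shift, 0 were called, and 100% of lists shifted by 0.5 log2 were. Since the simulated genes were not correlated, these values cannot show how often lists of correlated genes are called falsely.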

Results

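Fibroblasts that touch fibronectin through the pores of a membrane extend pseudopodia across it, and the membrane then keeps these protrusions apart from the cell bodies, which hold the nucleus. The arrays ask which RNAs differ in share between the compartments. There were 2 arrays of pseudopodia and 2 of cell bodies. The series' design text calls the samples of each compartment independent, but nothing says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Across the 11320 tested genes, log2 values correlated at 0.983 between the pseudopodia arrays, at 0.984 between the cell body arrays and at 0.949 to 0.957 between arrays of different compartments. These correlations are across genes, which are not independent replicates. The SD of the log2 difference between arrays was 0.352 and 0.357 within a compartment and 0.584 to 0.634 between compartments.

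The RNA content of pseudopodia differed from that of cell bodies at 1654 of 11320 genes (14.6%). Of these, 670 were higher in pseudopodia, with a median log2 difference of 0.92, and 984 were lower, with a median of -1.14. The median difference over all tested genes was -0.0020 on the log2 scale, which cannot show a general shift, as the scaling between arrays is not given in the sources used here. Changes of at least 2-fold were more often losses than gains in pseudopodia, at 633 against 257 called genes. Regardless of the test, 1000 genes were at least 2-fold apart with no overlap of arrays, 313 of them higher in pseudopodia and 687 lower. All 1654 called genes had no overlap between compartments, as had 60.8% of all tested genes, against 33.3% by chance.

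Among the genes that rose most in pseudopodia was Trim12c, of the tripartite motif family, at an intensity of 216 ± 43.4 against 23.4 ± 3.2 in cell bodies (SD, n = 2). Its log2 difference was 3.14 (SE 0.20, adjusted p = 0.0166), a size that rests on a cell body level just over the floor of 20. Sp8, a zinc finger transcription factor, was at the floor on both cell body arrays and at least 8.51-fold higher in pseudopodia, where its intensity was 171 ± 18.4 (SD, n = 2). Others among the 12 largest rises were Nol8, which encodes a nucleolar protein, at 2.25 (SE 0.43, adjusted p = 0.0345), the nucleosome-binding Hmgn5 at 1.93 (SE 0.17), and Itgb3bp, which encodes a centromere protein, at 1.92 (SE 0.26). The size for Nol8 is uncertain, since 1 of its cell body arrays read 22.1, just over the floor. Gxylt1, a xylosyltransferase, rose by 1.91 (SE 0.25), Pggt1b, the beta subunit of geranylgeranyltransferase, by 1.88 (SE 0.21), and Rasa1, a GTPase-activating protein of Ras, by 1.85 (SE 0.25). Ammecr1 rose by 2.01, Nbeal1 by 1.90, Htatsf1 by 1.86 and the small GTPase Rab13 by 1.84. Among abundant genes, chosen after their values were seen, the acetyltransferase subunit Naa50 rose by 1.71 (SE 0.15), the podosome scaffold Sh3pxd2a by 1.60 (SE 0.15) and the mitochondrial fission factor Mff by 1.57 (SE 0.13).

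The deepest losses in pseudopodia included 4 genes at the floor on both pseudopodia arrays. Col25a1, a membrane-bound collagen, was at least 7.90-fold lower there, Fndc7 at least 6.70-fold, Tsx at least 6.68-fold and Klrc1, a receptor of natural killer cells, at least 5.14-fold. The other probe sets of Col25a1 and Klrc1 lay at the floor on all 4 arrays, and those of Fndc7 lay under the filter. Each of these losses thus rests on 1 dim probe set. Rpl12, a protein of the large ribosomal subunit, fell by 2.87 (SE 0.17, adjusted p = 0.0166), from 610.6 ± 3.54 in cell bodies to 83.4 ± 14 in pseudopodia (SD, n = 2). It rests on 1 probe set. The protein disulfide isomerase Pdia4 fell by 2.51 (SE 0.30) and the secreted glycoprotein Lgals3bp fell by 2.37 (SE 0.22). Sbno2, a transcriptional coregulator, fell by 2.34 (SE 0.17), and its 3 other probe sets all fell as well. Ggcx, the vitamin K-dependent carboxylase of the endoplasmic reticulum, fell by 2.38 (SE 0.24), while its other probe set had a log2 difference of 0.35. Ppp1r3e and the lipid transporter Abca2 fell as well, with log2 differences of -2.18 and -2.16. Kifc5b also fell, and its difference of -2.42 is uncertain in size, since 1 of its pseudopodia arrays lay at the floor.

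These gene calls depend on the fit of 4 arrays together. With any 1 array left out, limma called 0 genes, with 2797 to 2891 at an unadjusted p under 0.05 against 3553 with all arrays, and without the filter on low values it called 2 (3844). Quantile normalization made the directions nearly even, at 840 genes higher and 896 lower. Among the genes named in the text, Actb, Ggcx, Hmgcs1, Hnrnpr, Kif5b, Lif, Nbeal1, Son, Ttk, Wasl, Slc44a2 and Gas5 each had another probe set above the filter with a difference of the opposite sign. This check covered the genes named by the rule and the abundant genes, not the others named in the text, and it left out probe sets under the filter.

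**Figure D1:**
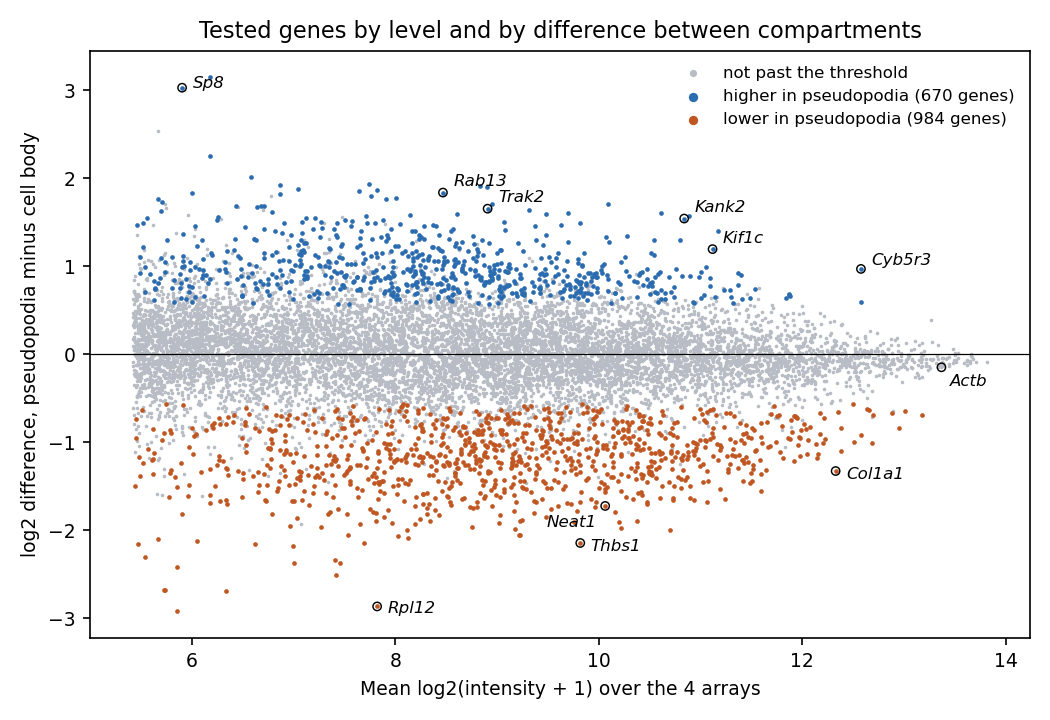
Each point is a tested gene, with the mean log2(intensity + 1) over the 4 arrays on the horizontal axis and the log2 difference, pseudopodia minus cell body, on the vertical axis. Coloured points are the 670 genes higher and the 984 lower in pseudopodia at an adjusted p of 0.05, and circled points are genes named on the plot.

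The RNAs known to gather in fibroblast protrusions were higher in pseudopodia as a group. Of 9 tested members, 8 rose, with a median of 1.19 on the log2 scale (2.29-fold), and 8 also rose adjusted over the list alone. Rab13, a small GTPase of membrane traffic, rose 3.57-fold (SE 0.15 on the log2 scale), from 187 ± 24.1 to 669 ± 26.8 (SD, n = 2). Trak2, an adaptor that links mitochondria to motors, rose 3.14-fold, Kank2, an adhesion-associated scaffold, 2.91-fold and Net1, an exchange factor for RhoA, 2.82-fold. The kinesin Kif1c rose 2.29-fold, the armadillo-repeat protein Pkp4 1.99-fold (adjusted p = 0.0201), the reductase Cyb5r3 1.96-fold and the dynein light chain Dynll2 1.60-fold (adjusted p = 0.0332). The other bright probe set of Dynll2 had a log2 difference of 0.0093 (adjusted p = 0.977 with each probe set tested on its own). The collagen receptor Ddr2 had a log2 difference of 0.28 (SE 0.20, adjusted p = 0.414) at its brightest probe set and of 1.58 at its other one (adjusted p = 0.0241 with each probe set tested on its own). Camera gave the list an adjusted p of 4.26e-07, and fry 0.00740. It was adjusted p = 0.624 with an estimated correlation. The list is in part chosen on these samples, so it is not independent evidence of its direction, and neither is the count adjusted over the list alone.

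Messages of the extracellular matrix and other secreted proteins were lower in pseudopodia. Of 35 tested members, 24 fell and 0 rose (29 fell adjusted over the list alone), 34 had differences below 0, and the median was -0.92, which is 1.89-fold higher in cell bodies. The matrix glycoprotein thrombospondin 1 (Thbs1) fell by 2.15 (SE 0.16) on the log2 scale. The basement membrane collagens Col4a2 and Col4a1 had differences of -1.91 and -1.71 (SE 0.17 for each), and Col6a3 fell by 1.66 (SE 0.16). Col1a1 fell by 1.33 (SE 0.16) and Col1a2, the brightest member, fell by 0.69 (SE 0.13), while its other probe sets had differences of -1.54 and -1.42 (adjusted p = 0.0245 and 0.0699 with each probe set tested on its own). The member above 0 was the proteoglycan Hspg2, with a log2 difference of 0.49 (SE 0.46, adjusted p = 0.540). The camera test gave an adjusted p of 4.91e-13, and adjusted p = 0.657 with an estimated correlation. The adjusted p was 0.0808 by fry.

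The machinery that imports and folds such proteins in the endoplasmic reticulum went the same way. Of 35 tested members, 19 fell and 0 rose (27 fell adjusted over the list alone), with a median of -0.66, or 1.58-fold higher in cell bodies. Beside Pdia4, the disulfide isomerase Pdia6 fell by 1.98 (SE 0.17) and the collagen prolyl hydroxylase P4ha2 fell by 1.68 (SE 0.14). Rpn2 and Ddost, both of the oligosaccharyltransferase, fell with differences of -1.64 (SE 0.14) and -1.44 (SE 0.15). P4hb, the brightest member, fell by 0.64 (SE 0.14). Camera gave an adjusted p of 8.47e-11, with adjusted p = 0.657 with an estimated correlation and 0.0808 by fry. The mean log2 ratio of 3' to 5' signal was higher in pseudopodia for the mRNA controls Actb, pyruvate carboxylase and Gapdh, by 0.24, 0.069 and 0.026. Only that of 18S ribosomal RNA, which is not an mRNA, was lower. The log2 ratio of 3' to 5' signal of Actb was 0.56 and 0.65 on the pseudopodia arrays and 0.37 and 0.36 on the cell body arrays, while that of 18S ribosomal RNA was 2.46 and 1.35 against 2.77 and 3.06.

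**Figure D2:**
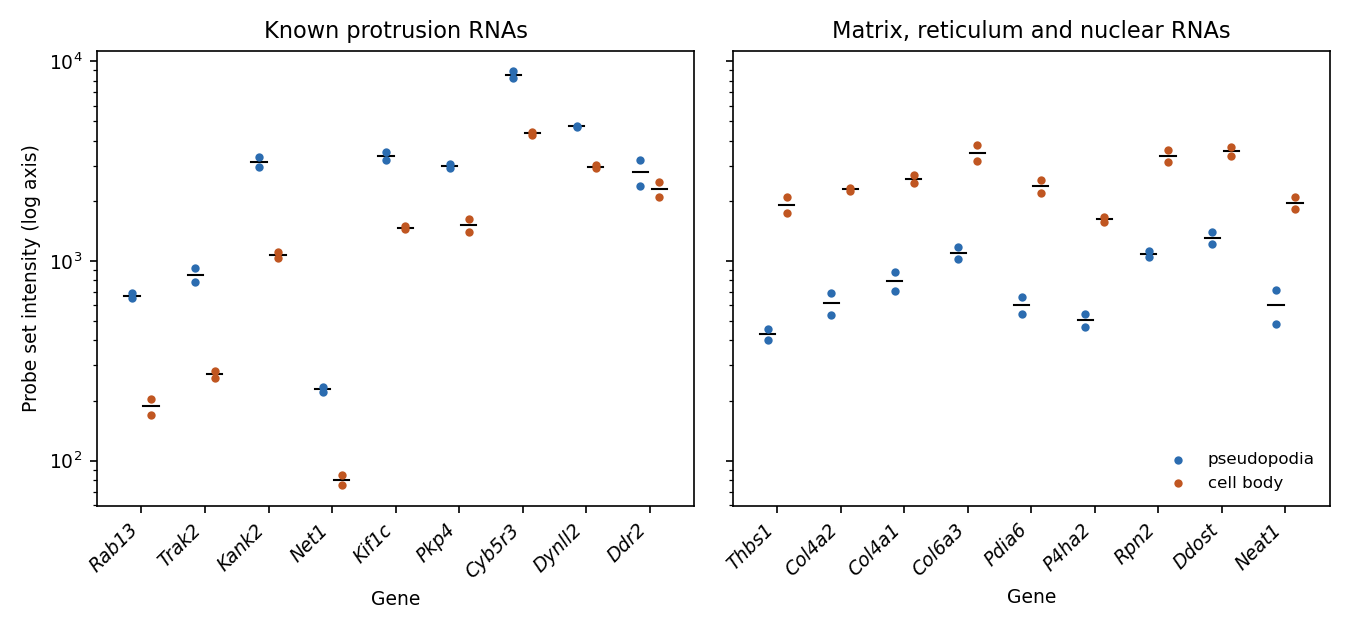
Probe set intensity of each array on a log axis, with pseudopodia and cell body arrays as points beside each other and their means as bars, for 9 protrusion RNAs and for 9 RNAs of matrix, endoplasmic reticulum and nucleus. The pseudopodia arrays lie above the cell body arrays for 8 of the protrusion RNAs, the exception being Ddr2, and below them for all 9 others.

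Immediate early and other short-lived transcripts were lower in pseudopodia by a smaller amount. Of 55 tested members, 11 fell and 0 rose (13 fell adjusted over the list alone), 47 had differences below 0, and the median was -0.39. The matricellular growth factor Ccn2 fell by 1.38 (SE 0.16), and the cytokine Lif and the chemokine Ccl2 had differences of -1.26 and -1.21 (SE 0.17 for each). The other probe set of Lif had a difference of 0.68 (adjusted p = 0.146 with each probe set tested on its own). Zfp36, which promotes mRNA decay, fell by 0.96 (SE 0.14). Fos had a log2 difference of -0.68 (adjusted p = 0.216), and Nfkbia, the brightest member, of -0.21. Camera gave an adjusted p of 9.32e-06, with adjusted p = 0.624 with an estimated correlation and 0.0808 by fry. The same differences in 3' to 5' signal of Actb and 18S ribosomal RNA lie between these arrays.

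Markers of fibroblasts and genes of cell adhesion also lay lower in pseudopodia as lists. The fibroblast list shares 4 tested genes with the matrix list, so its shift is in part the same result. Among 14 fibroblast markers, 4 fell (7 adjusted over the list alone), with a median of -0.43: Col1a1 and Col1a2, which the matrix list shares, and the growth factor receptors Pdgfrb, at -1.21 (SE 0.20), and Pdgfra, at -1.18 (SE 0.23). Lgals1, the brightest member, had a log2 difference of -0.09 (adjusted p = 0.673) at a probe set near the top of the intensity scale, which may hide a difference. The list's adjusted p was 0.0141 by camera and 0.140 by fry, and adjusted p = 0.657 with an estimated correlation. Among 34 focal adhesion genes, 7 fell and 1 rose (the same numbers adjusted over the list alone), with a median of -0.18. The fibronectin receptor subunits Itga5 and Itgb1 fell, with differences of -1.73 and -1.07 (SE 0.16 for each), as did the actin crosslinkers Flnc and Flna, at -1.14 and -0.96 (SE 0.14 for each), while the adaptor Lims1 rose by 0.82 (SE 0.18). Camera gave the adhesion list an adjusted p of 0.0476, and adjusted p = 0.657 with an estimated correlation; fry gave 0.0276. That camera call was lost with a stricter filter (adjusted p = 0.146), quantile normalization (0.120), median centring (0.0532) and without probe sets that match several transcripts (0.0541), and it was lowest without a filter (0.00761). It was also lost without pseudopodia replicate 1 (0.0605), pseudopodia replicate 2 (0.0753) or cell body replicate 2 (0.126).

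Cytoskeletal and membrane-traffic lists held genes that changed, while the lists did not pass the threshold in the main setting. Of 67 microtubule and motor genes, 8 rose and 2 fell (the same numbers adjusted over the list alone). Among those that rose, Kif1c and Dynll2 also belong to the known protrusion RNAs, a list in part chosen on these samples. The dynein light chain Dynlt3 rose by 1.60 (SE 0.16) and the kinesin heavy chain Kif5b by 1.03 (SE 0.13), while the dynein heavy chain Dync1h1 fell by 1.16 (SE 0.15). The list's adjusted p was 0.150, but 0.0191 with each probe set on its own, and up to 0.657 under the others. Of 42 actin and Arp2/3 genes, 5 rose (4 adjusted over the list alone), among them the filament elongator Enah by 0.96 (SE 0.15), the nucleation promoter Wasl by 0.85 (SE 0.17) and the capping protein subunits Capza2 by 0.79 (SE 0.15) and Capza1 by 0.73 (SE 0.14), at a list adjusted p of 0.195. Quantile normalization brought that to 0.0383, and the other settings gave 0.0901 to 0.905. Of 45 Rab GTPases, 3 rose and 1 fell, also adjusted over the list alone: Rab13, Rab8b by 1.06 (SE 0.14) and Rab5a by 1.00 (SE 0.14) rose, and Rab5b fell by 1.11 (SE 0.21), at a list adjusted p of 0.129. That was 0.0272 with a stricter filter and 0.0376 with each probe set on its own, and up to 0.905 under the others. Rab13 is also one of the known protrusion RNAs, so its rise is not a separate result. Actb itself, the main actin of these cells, had a log2 difference of -0.15 (SE 0.13, adjusted p = 0.494) at a probe set near the top of the intensity scale, and of 0.85 at a dimmer one (adjusted p = 0.0777 with each probe set tested on its own). Gapdh had no probe set of its own outside the controls, and its 3' control probe set read 10445 and 9827 on the pseudopodia arrays and 10753 and 10883 on the cell body arrays.

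The genes of protein synthesis and of mitochondria did not pass the test as groups in the main setting. Rps29 and Tpt1, the brightest ribosomal protein gene and translation factor, read near the top of the intensity scale, which may hide a difference. Of 43 cytoplasmic ribosomal protein genes, 1 rose, Rps6 by 0.87 (SE 0.14), and 1 fell, Rpl12, also adjusted over the list alone, at a list adjusted p of 0.818, which was 0.0466 without a filter and up to 0.983 under the others. Of 31 translation factors, 4 rose (5 adjusted over the list alone), Eif3m by 0.90 (SE 0.16), Eif1a by 0.84 (SE 0.13), Eif5b by 0.81 (SE 0.13) and Eif3e by 0.59 (SE 0.13), at a list adjusted p of 0.548. With each probe set on its own it was 0.010 and the median turned to 0.050, and the others gave up to 0.978. Of 76 mitochondrial ribosomal protein genes, 3 rose (1 adjusted over the list alone), Mrpl47 by 1.15 (SE 0.14), Mrps18c by 0.91 (SE 0.14) and Mrps22 by 0.63 (SE 0.13). The list's adjusted p was 0.114, but 0.00179 with quantile normalization, 0.0207 with a stricter filter, 0.0421 with none, 0.0388 without pseudopodia replicate 2 and 0.0439 without cell body replicate 2, and up to 0.905 under the others. Of 74 oxidative phosphorylation genes, 1 rose (0 adjusted over the list alone), Ndufa5 by 0.58 (SE 0.13), at a list adjusted p of 0.548.

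The list of nuclear-retained noncoding RNAs showed no shift past the test as a group. As fixed, it was mixed: it included Gas5 and Snhg transcripts, which are also cytoplasmic, and Slc7a2, the gene of a nuclear RNA. It therefore cannot show whether nuclear RNAs as a class differ between the compartments. Of 14 tested members, several of them held in the nucleus, 1 fell (2 fell and 2 rose adjusted over the list alone). That was Neat1, the scaffold of paraspeckles, which fell by 1.73 (SE 0.23, adjusted p = 0.0183), while its second probe set had a log2 difference of -0.17. Malat1 had a log2 difference of -0.18 (adjusted p = 0.634), Snhg3 of -1.17 (adjusted p = 0.0721), Kcnq1ot1 of -1.08 (adjusted p = 0.149), Pvt1 of 0.59 (adjusted p = 0.0560) and Gas5 of 0.68 (adjusted p = 0.0641). A pair of other Gas5 probe sets, both dimmer, had differences of -1.82 and -1.79 (adjusted p = 0.0251 and 0.0279 with each probe set tested on its own). Another bright Gas5 probe set had a difference of 0.79 (adjusted p = 0.102 in the same way). The list's adjusted p was 0.918. Of 75 splicing factors, 7 rose and 2 fell (0 adjusted over the list alone), with Luc7l3 up by 1.27 (SE 0.19) and Hnrnpr up by 0.88 (SE 0.15), while Son fell by 0.70 (SE 0.13), at a list adjusted p of 0.548. Of 186 genes named as zinc finger proteins, 17 rose and 8 fell (16 and 7 adjusted over the list alone), with Zfp931 up by 1.80 (SE 0.17) and Zfp959 up by 1.47 (SE 0.15), at a list adjusted p of 0.172. Zfp36 is among those that fell, and it belongs to another class of zinc finger protein that binds RNA.

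Further lists gave these counts. Of 29 mitosis genes, 3 rose and 3 fell (3 and 5 adjusted over the list alone): Nusap1 by 0.98, Ttk by 1.00 and Bub1 by 0.80 rose, and Plk1, Aurka and Cdc20 fell, at -0.82, -0.73 and -0.57. Of 30 DNA replication genes, 2 rose, Ccne2 by 1.13 and Pola1 by 0.72, also adjusted over the list alone. Of 17 cholesterol synthesis genes, 2 rose (Hmgcs1 by 0.90 and Idi1 by 0.76) and 5 fell (6 adjusted over the list alone), among which Msmo1 decreased by 1.05 and Sqle decreased by 0.97. Of 12 glycolysis genes, 1 fell, also adjusted over the list alone: the glucose transporter Slc2a1, which fell by 1.16 (SE 0.14). Of 36 proteasome genes, 2 rose (1 adjusted over the list alone), Psmc6 by 1.10 and Psmd6 by 0.64, and of 21 cytosolic chaperones 1 rose, Dnaja1 by 0.81, also adjusted over the list alone. Of 5 replication-dependent histone genes, 0 passed the test by either adjustment. The list adjusted p was 0.473 for mitosis, 0.728 for DNA replication, 0.150 for cholesterol synthesis, 0.359 for glycolysis, 0.818 for the proteasome, 0.643 for chaperones and 0.918 for histones. With each probe set on its own it was 0.0373 for mitosis and 0.0451 for glycolysis, both up to 0.967 under other settings, and without a filter 0.0466 for cholesterol synthesis, up to 0.905 under others.

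Of the 25 lists tested, 6 passed the threshold by camera, 0 with an estimated correlation and 2, the protrusion and adhesion lists, by fry. The form with an estimated correlation had only 2 residual degrees of freedom, so it cannot show that the shifts are absent. For 5 lists the median, mean and test differed in sign: translation factors, nuclear-retained noncoding RNAs, splicing factors, replication-dependent histones and the proteasome. Quantile normalization also turned the sign of the median for cytoplasmic ribosomal proteins, translation factors, glycolysis, noncoding RNAs, splicing factors and the proteasome.

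**Figure D3:**
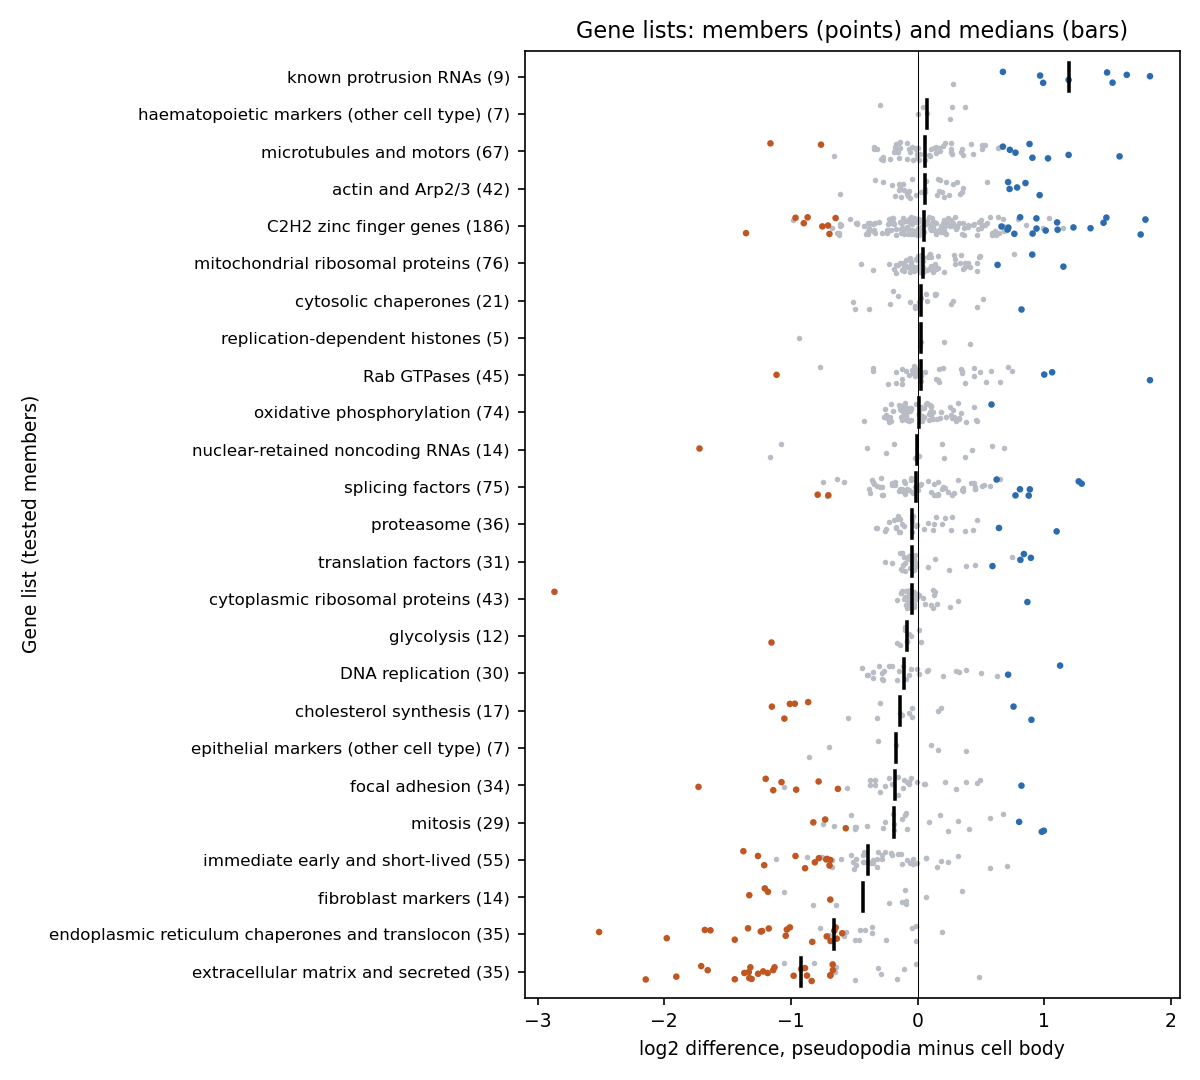
Each point is a tested gene of a list, placed by its log2 difference, pseudopodia minus cell body, with the number of tested members beside the list's name and the median as a bar. Coloured points passed the adjusted p of 0.05; the medians run from -0.92 for matrix genes to 1.19 for known protrusion RNAs.

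Markers of other cell types did not differ between the compartments past the test. Of 7 epithelial markers above the filter, 0 passed over all genes and 2 fell adjusted over the list alone; Epcam had a log2 difference of -0.86 (adjusted p = 0.0721) and Cldn4 of -0.70 (adjusted p = 0.0714), and the list's adjusted p was 0.548. Of 7 haematopoietic markers, 0 passed by either adjustment, with Adgre1 at 0.38 (adjusted p = 0.120) and a list adjusted p of 0.548. The log2 ratio of 3' to 5' signal differed by 0.026 between compartments for Gapdh and by 0.069 for pyruvate carboxylase, against 0.24 for Actb and -1.01 for 18S ribosomal RNA. The spike-in controls BioB, BioC and BioD read higher on the pseudopodia arrays, by 0.49, 0.43 and 0.20 on the log2 scale, and Cre differed by -0.0063.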

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

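All tests of explanations in this part were chosen only after the result was seen, although no Slc25 value had been looked at when that family was chosen. Signal also changed in probe sets that the gene-level comparison does not use. When each probe set was tested on its own, 55 of 2554 unnamed probe sets above the filter were higher in pseudopodia and 218 were lower, and of 580 probe sets shared by several genes 41 were higher and 23 lower. The middle probe set of 18S ribosomal RNA, a control outside the comparison, read 1970 on pseudopodia replicate 2, against 308 on pseudopodia replicate 1 and 172 and 111 on the cell body arrays.

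The loss of matrix and endoplasmic reticulum messages from pseudopodia covered 43 of 70 tested genes, with a median log2 difference of -0.79 (adjusted p = 0.255 with an estimated correlation). If degraded RNA had removed signal far from the 3' end, the probe set nearest that end would lie near 0; its position was not used here, and the least lowered probe set of each gene stands in for it, but over 47 genes with several probe sets its median was -0.56 (95% bootstrap interval -0.67 to -0.35). Scaling that depends on intensity would lower other genes of the same brightness alike, but 95% of random lists matched on level had medians between -0.13 and 0.0052; both values argue against these as the whole cause, the first only where a gene has a probe set near its 3' end, and matched lists treat genes as independent. A candidate explanation is that mRNAs translated on the endoplasmic reticulum stay in the cell body; it predicts that membrane carriers made there lie lower than the mitochondrial carriers of the Slc25 family, which are made in the cytosol, and the medians were -0.61 over 165 genes and -0.0044 over 35, a difference of -0.61 (permutation p = 0.00283, two-sided, 100000 permutations). This remains a hypothesis found and tested on the same arrays: falling solute carriers had been seen before that family was chosen, the permutation treats genes as independent, the solute carriers outside Slc25 had adjusted p = 0.255 with an estimated correlation, and unequal recovery of the reticulum itself through the pores and fixation was not tested.

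Short-lived transcripts were lower in pseudopodia with a median log2 difference of -0.39 over 55 genes, outside the range of -0.15 to 0.06 that held 95% of lists matched on level, which treat genes as independent. The whole list had adjusted p = 0.624 with an estimated correlation. Since 9 members encode secreted or membrane-bound products, which had a median of -0.78, these could carry the shift, but the other 46 members had a median of -0.35 against -0.16 to 0.07 for matched lists (adjusted p = 0.255 with an estimated correlation). Both values argue against scaling and against the secreted members as the whole cause. A biological difference between the compartments and a 3' bias of the pseudopodia RNA both stay open, and neither was tested for this list.

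The BioB spike-in was brighter on the pseudopodia arrays by 0.49. The 1826 genes within 0.5 log2 of it had a median difference of 0.013 (95% interval -0.02 to 0.04). Since the unstated scaling of the deposited values can hold that median near 0, a shift shared with the genes cannot be told apart from one of the spike-ins alone, and no biological explanation was tested.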

How the results depend on the processing

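All alternatives were planned except the setting with only genes above the floor, whose test was chosen only after the result was seen. The count of 1654 called genes (670 higher and 984 lower) stayed within 1.5 times under the stricter filter (2031), quantile normalization (1736, with 840 higher and 896 lower), median centring (1911), a pseudocount of 16 (1889), the mean of a gene's probe sets (1488), no shared probe sets (1604) and genes above the floor (1683). Without the filter it was 2 (0 higher, 2 lower), with 18193 genes tested and 0.491 prior degrees of freedom; which of these ended the calls was not tested. It was 2645 with each probe set on its own (1676 lower), 2575 with trended and robust variance (1092 and 1483) and 2749 at an adjusted p of 0.10 (1253 and 1496). It was 0 in both directions with a plain t-test (2554 at an unadjusted p under 0.05) and with treat at 1.5-fold (1084). With each array left out in turn, limma's count ran from 0 to 0 in total and in each direction (2797 to 2891 at an unadjusted p under 0.05), with 1 residual degree of freedom and the lone array assumed to vary like the other group. The 1000 genes at least 2-fold apart became 627 under the stricter filter, which tests fewer genes, and 2378 with each probe set on its own, which tests more. With 1 array left out, a lone array overlaps the others less easily. That count can then rise by construction, so it cannot show how steady the 1000 are. Of the 6 gene lists past the threshold, 0 remained with an estimated correlation and 2 by fry, and 11 lists passed with each probe set on its own; without 1 array 5 to 6 passed. Where no construction is named, the cause was not tested. No called list or named gene reversed. Over the other settings, 15 list values and 341 values of named genes lost their call, and 12 and 69 gained one; with an array left out, 3 list values and 412 gene values lost it and 2 list values gained one. A scan batch was not run, since all arrays share 1 scan day. The floor of 20 limits the size of differences of dim genes.

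The labels do not show that same-numbered arrays share a culture. The deviations of same-numbered arrays correlated at 0.342 across genes, with only 2 pairs. Between replicates 1 and 2, 2980 genes had no overlap of arrays, and 86 of them were at least 2-fold apart. For the crossed pairs these counts were 1457 and 17. Same-numbered arrays thus deviated together, which the unpaired main fit leaves out, and what they share is not given in the sources used here. With the replicate block, 2202 genes were called (44.9% higher), 1649 of them among the 1654. The focal adhesion list was then past the threshold no longer, at an adjusted p of 0.0556, and no other list call changed.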

Other observations

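The tests of the solute carrier and transmembrane families were chosen only after the result was seen. Transporters of the plasma membrane and other organelles were lower in pseudopodia. Of 165 solute carrier genes outside Slc25, 70 fell and 1 rose, with a median of -0.61 on the log2 scale, while 95% of random lists matched on level had medians between -0.06 and 0.10. The amino acid transporter Slc7a6, the vitamin C transporter Slc23a2 and the iron transporter Slc11a2 fell, with differences of -1.68, -1.62 and -1.49 (SE 0.13 for each). Slc44a2, a choline transporter, fell by 2.00 (SE 0.15), though 1 of its probe sets had a log2 difference of 0.08. Over 6 lists tested in this way, its adjusted p was 1.67e-13 by camera, and adjusted p = 0.255 with an estimated correlation. Of 35 mitochondrial carriers, 0 fell and 1 rose, Slc25a46, by 0.68 (SE 0.14).

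Genes named Tmem, for transmembrane proteins, were lower by less. Of 151 tested, 30 fell and 3 rose, with a median of -0.21 against -0.07 to 0.09 for matched lists. Tmem9 fell by 1.88 (SE 0.18) and Tmem43, a protein of the nuclear envelope and endoplasmic reticulum, fell by 1.85 (SE 0.13). The camera adjusted p was 2.21e-04, and adjusted p = 0.379 with an estimated correlation.

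Brightness and direction went together, to a small degree in the medians and more clearly among called genes. At a mean log2 of 6 to 7, 90 genes were called higher in pseudopodia and 90 lower. At 10 to 11 these counts were 62 and 172, and at 11 to 12 they were 23 and 97. The median log2 difference was 0.09 for the 1156 genes from the filter to a mean log2 of 6, and -0.08 for the 494 genes above a mean log2 of 12, of which 2 were called higher in pseudopodia and 28 lower.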
